A study of Mus musculus with 6 samples.

How the data were processed

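The samples were 6 libraries of nuclei from subcutaneous white adipose tissue, 3 from flox control and 3 from Treg knockout mice, with 1 library per replicate. Per the labels, the nuclei were isolated on a sucrose gradient, sorted on DAPI, and made into 10x Genomics 3′ libraries, with 3 mice per genotype. The deposited matrix of each library holds UMI counts per gene and barcode, which the authors made with Cell Ranger 7.1. The other deposited files hold names only: the barcodes and the genes in the order of each matrix. The authors' notes name the builds mm10 and GRCh38, while all 32285 genes in the files are mouse genes. Whether intronic reads were counted, how barcodes were filtered after Cell Ranger (the lowest barcode total was 500 UMIs), and which exons of Gpsm1 were deleted are not given in the sources used here. Positions are from GENCODE vM21 on mm10, which covered 99.6% of the genes by identifier.

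Nuclei with at least 500 detected genes and at most 5% mitochondrial UMIs were kept. Of the barcodes of flox controls 1, 2 and 3, 188, 209 and 654 fell below the first limit and 472, 235 and 324 above the second. In knockouts 1, 2 and 3 these were 176, 209 and 123, and 630, 453 and 235. Scrublet scores were computed per library in scanpy 1.11.5, and the highest-scoring barcodes were removed at a fixed rate of 0.8% per 1000 barcodes (926, 851 and 991 in the controls, 1054, 951 and 895 in the knockouts). The threshold that the tool sets itself called 0 in flox control 3. These limits and this rate were set before their effect was seen but were not part of the written design. In all 56226 of 65162 barcodes were kept. No library looked like a copy of another: between libraries of a group the chi-square per degree of freedom over genes was 32.5 to 79.9, and every pair shared few barcodes. The replicate numbers were not treated as pairs.

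Counts were scaled to the nucleus total and log-transformed, 3000 variable genes and 40 principal components were taken, and a shared-neighbour graph of 20 neighbours was clustered with the Leiden method (igraph 0.11.9, leidenalg 0.10.2) at resolution 1, which gave 39 clusters. No integration across libraries was used. Clusters were named by 17 marker lists. A cluster took a name when at least 3 markers, and at least 50% of the list, stood at least 2-fold above the mean of the other clusters (with 5 CPM added), and no other list reached 33%, related lineages apart. Clusters whose 10 leading genes held more markers of another list, or with low UMIs and no marker among them, were not named. The comparison with the mean of the other clusters, both percentages and these exceptions were settled after seeing the markers and the cluster sizes per library, over several tries. They left 9 clusters unnamed, with 2.97, 2.05 and 33.3% of kept nuclei in controls 1, 2 and 3 and 3.48, 3.24 and 9.15% in knockouts 1, 2 and 3 (12.8 ± 17.8% against 5.29 ± 3.34%; SD, n = 3). Assigning each nucleus by its own marker score gave the same class for 88.7% of named nuclei. The word "like" marks classes that rest on markers alone.

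The UMIs of each class were summed per library, so that a library is 1 replicate. In the summed whole tissue the libraries held 48294372, 48605464 and 40814518 UMIs in controls 1, 2 and 3 and 33427869, 33200406 and 35522426 in knockouts 1, 2 and 3. The adipocyte-like sums ran from 14541459 to 31331860 UMIs, the ASPC-like from 4674028 to 7609966, the macrophage-like from 2360206 to 7274895 and the endothelial-like from 715666 to 2311813. The T-cell-like sums ran from 103967 to 1250915 and the mural-like from 139976 to 532828. Classes with at least 20 nuclei in each library were tested.

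Changed genes were tested with edgeR 4.0.16 in R 4.3.3 (robust quasi-likelihood fit, TMM factors, filterByExpr by group), with Benjamini-Hochberg adjustment over the genes of a class and a threshold of 0.05. Log2 fold changes are knockout over control. Shares of nuclei in 13 classes were tested with edgeR on nuclei per library, with all kept nuclei of the library as the offset. Shares of positive nuclei and levels of single genes were compared by an exact two-sided permutation test over the libraries, whose smallest p is 0.1 with 3 against 3, and shares have 95% Clopper-Pearson intervals. Foxp3-positive means at least 1 UMI. Positive nuclei were also counted after thinning each nucleus to 1000 UMIs, and with at least 2 of 6 Treg genes.

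The 24 gene lists and the marker lists were fixed before the data were examined, as were the comparisons, the tests, the alternatives to them and the rule for naming genes. The gene lists were thermogenic adipocyte, futile creatine and calcium cycling, de novo lipogenesis, triglyceride synthesis, lipolysis and beta-adrenergic, fatty acid oxidation, nuclear-encoded oxidative phosphorylation, insulin signalling and glucose uptake, adipokines, adipogenic transcription factors, extracellular matrix and fibrosis, inflammatory cytokines and chemokines, interferon response, lipid-associated macrophage, resident macrophage, MHC class II presentation, Treg signature, effector T cell, adenosine axis, hypoxia, immediate early and heat shock, proliferation, senescence, and angiogenesis. Each list with at least 5 measured genes was tested by camera (limma 3.58.1, preset correlation 0.01) on log CPM with a prior count of 2, with adjustment over 143 tests. It was also tested by fry and by camera with an estimated correlation. A list of sex-linked genes served only to compare the libraries: Xist had 9 to 15 and Ddx3y 4959 to 6854 UMIs in each library, and no library stood apart.

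Genes were named by rule: in each class the 10 largest folds up and the 10 largest down among genes past the threshold with a mean of at least 20 CPM, whose 3 libraries of one group all lay above the 3 of the other, with predicted genes (Gm and Rik) passed over. List members that passed, and 19 genes tied to the study's question whatever their values, could also be named, and where fewer than 3 genes passed, the 5 with the smallest p were named as not having passed. For the 19 genes the text gives the classes in which each is known to act.

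On simulated counts with the depth and spread of each class, a 2-fold change was recovered for 51.6% of genes in whole tissue, 70.1% in adipocyte-like, 73.4% in ASPC-like, 71.2% in macrophage-like, 56.1% in endothelial-like, 72.4% in T-cell-like and 39.3% in mural-like sums. Between 3.6% and 8.9% of calls were false. For the shares, a 3-fold change was recovered in 100% of 50 simulations with 1% false calls, at a simulated coefficient of variation of 22.4%, which several measured shares exceed (B-cell-like 2.70 ± 2.09% in the controls, SD), and recovery at that spread was not simulated. In simulated adipocyte-like sums with a gene length trend, uncorrected tests made 3765 false calls and length-corrected tests 5.

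Alternatives planned beforehand were RLE factors, library totals alone, DESeq2 1.42.0, no filter on low counts, a replicate block, leaving out each library, no doublet removal, at least 1000 genes, Leiden resolution 2, classes by marker score, TMM factors for the shares, and other definitions of Treg nuclei. Added after seeing the data were the adipose classes alone, removal of each library's trend over gene length, nuclei within a shared window of UMIs (3000 to 8000 in adipocyte-like and 1500 to 5000 in macrophage-like nuclei), and the list tests at resolution 2 and with at least 1000 genes. Nuclei of unnamed clusters entered only the whole-tissue sums and the total of kept nuclei. The makeup of a class by cluster was taken over the pooled nuclei of a group, without a test or a spread between libraries. Sequence reads were not used here. Computation outside R used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.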

Results

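Nuclei of subcutaneous white adipose tissue were profiled by droplet-based single-nucleus RNA sequencing after the mice had been fed a high-fat diet, for 12 weeks by the sample labels, while the protocol gives 5 to 12 weeks. The 6 libraries formed 2 groups of 3. Flox control libraries came from GPSM1f/f mice, whose Gpsm1 gene is flanked by loxP sites, and Treg knockout libraries came from GPSM1ΔTreg mice, in which, by the name of the genotype, the gene is deleted in regulatory T cells (Treg cells). The deposited matrices of flox controls 1, 2 and 3 held 55342903, 55250025 and 45007561 unique molecular identifiers (UMIs) in 10756, 10314 and 11132 barcodes. Those of knockouts 1, 2 and 3 held 39130112, 38857282 and 41951373 UMIs in 11480, 10901 and 10579 barcodes. All 3 control libraries were deeper than all 3 knockout libraries (exact two-sided permutation p = 0.1, the smallest that 3 against 3 libraries can give). After filtering, 9296, 9113 and 9314 control nuclei and 9729, 9416 and 9358 knockout nuclei were kept, with median UMIs per nucleus of 3165.5, 3198 and 2471.5 in the controls and 2054, 2443.5 and 2588 in the knockouts.

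The series title concerns a restriction of CD73- and CD103-bearing Treg cells by GPSM1, a G-protein signalling modulator, so the targeted gene and the Treg cells come first. In T-cell-like nuclei, Gpsm1 (ENSMUSG00000026930; mm10 chromosome 2, 26315515 to 26348237) averaged 35.01 ± 19.9 CPM (UMI counts per 1e6) in the controls and 15.4 ± 6.22 in the knockouts (SD, n = 3 libraries). With the clusters used throughout, all 3 knockout libraries lay below all 3 controls, with 27.0, 57.7 and 20.3 CPM in controls 1, 2 and 3 and 19.2, 8.20 and 18.8 in knockouts 1, 2 and 3 (exact two-sided permutation p = 0.1). These levels rest on 16 Gpsm1 UMIs in the controls and 42 in the knockouts. The difference in the Gpsm1 level in T-cell-like nuclei was -19.6 CPM and became -8.28 without flox control 2. The groups overlapped at Leiden resolution 2 and with classes by marker score (exact permutation p = 0.4 for both), and with nuclei of at least 1000 genes (exact permutation p = 0.5). The gene was too low for the edgeR test in this class. The deletion is expected only in Treg cells, a small part of this class, and the labels do not say which exons were removed, so 3′ tags of a deleted allele may still be counted. Across the whole tissue Gpsm1 did not pass the test (log2 fold change 0.34, adjusted p = 0.122), nor did it in adipocyte-like nuclei (0.37, adjusted p = 0.129).

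Foxp3, the transcription factor that defines Treg cells, was detected in too few T-cell-like nuclei to tell whether its share differed between the groups. The share was 3.85 ± 1.30% in the controls and 3.29 ± 1.25% in the knockouts (SD, n = 3; exact permutation p = 0.8). In flox controls 1, 2 and 3 it was 4.92% (95% Clopper-Pearson interval 1.83 to 10.4), 4.23% (0.880 to 11.9) and 2.40% (0.498 to 6.85). In knockouts 1, 2 and 3 it was 4.73% (3.30 to 6.55), 2.43% (0.897 to 5.21) and 2.72% (1.41 to 4.69). These intervals overlap and cover counting error only, so a difference was not detectable at this depth. Adipocyte-like nuclei, which should lack Foxp3, had a UMI of it in 0.353% of control and 0.131% of knockout nuclei at median depths of 10178, 9397.5 and 9362 against 8628.5, 5231 and 5918 UMIs. The T-cell-like nuclei had medians of 1431, 1308 and 1882 against 1594, 1325 and 1672 UMIs.

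Because T-cell-like nuclei were more numerous in the knockouts, 12 of 318 control and 52 of 1408 knockout nuclei of this class were Foxp3-positive, or 4.32 ± 1.85 and 18.05 ± 14.99 per 10000 kept nuclei (SD, n = 3; exact permutation p = 0.2). Of these Foxp3-positive nuclei, 5 in the controls and 24 in the knockouts had a UMI of Nt5e, which encodes CD73, the ectonucleotidase that makes adenosine from AMP. Itgae, which encodes CD103, the integrin chain that binds E-cadherin, was seen in 0 of 12 control nuclei, which allows a share of up to 25% with a UMI, and in 19 of 52 knockout nuclei. Knockout 1 alone gave 18 of the 24 and 15 of the 19. No background share was measured for Nt5e or Itgae. Over all T-cell-like nuclei, the Nt5e-positive share was 11.1 ± 2.17% in the controls and 15.1 ± 5.87% in the knockouts, and the Itgae-positive share was 12.4 ± 4.48% and 11.5 ± 3.39% (exact permutation p = 0.4 and 0.7). In the edgeR test of this class, neither Nt5e (log2 fold change 0.80, SE 0.325, adjusted p = 0.230) nor Itgae (0.43, SE 0.329, adjusted p = 0.620) passed. Il2ra, the receptor chain for interleukin 2, was at 0.00, and Ikzf2, which encodes Helios, was at 0.28 (adjusted p = 0.998 and 0.433).

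**Figure D1:**
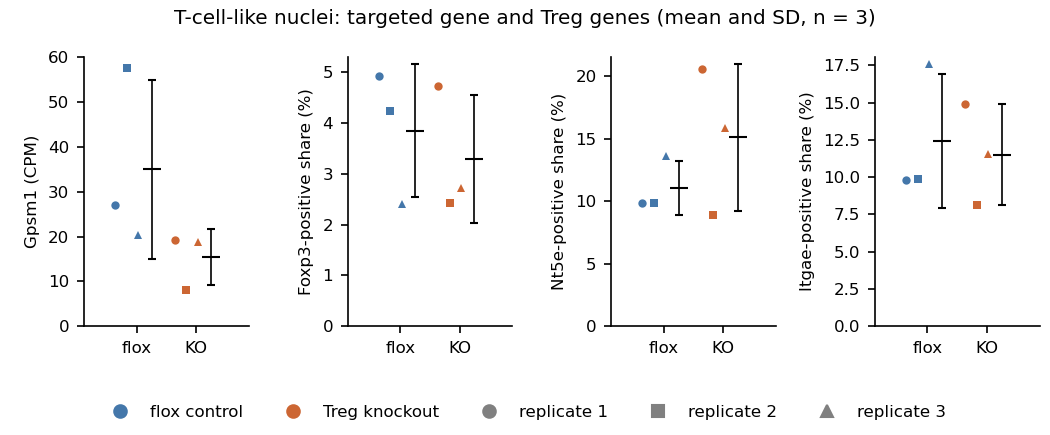
Gpsm1 level (CPM) and the percentage of T-cell-like nuclei with a UMI of Foxp3, Nt5e or Itgae in each library, as points, with the mean and SD of each group (n = 3) in black. With these clusters the 3 knockout libraries lie below the 3 controls for Gpsm1, which does not hold at Leiden resolution 2, with classes by marker score or with at least 1000 genes, and the groups overlap for Foxp3, Nt5e and Itgae.

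The shares of nuclei differed between the groups, and whether lymph node tissue in the samples gave rise to this stays open. B-cell-like nuclei rose from 2.70 ± 2.09% of kept nuclei in the controls to 23.3 ± 13.5% in the knockouts (SD, n = 3), with 2.02, 1.03 and 5.05% in controls 1, 2 and 3 and 38.3, 12.3 and 19.1% in knockouts 1, 2 and 3. T-cell-like nuclei rose from 1.14 ± 0.317% to 4.91 ± 2.39%. The edgeR log2 fold changes were 3.11 (SE 0.789) for B-cell-like and 2.10 (SE 0.541) for T-cell-like nuclei, both with an adjusted p of 0.0455 over 13 classes, and all 3 knockout libraries lay above all 3 controls for both. No other class passed. Mural-like nuclei, the contractile cells around vessels, were 1.91% and 0.767% (log2 fold change -1.32, adjusted p = 0.0578), endothelial-like nuclei 9.68% and 4.55% (-1.09, 0.111), and macrophage-like nuclei 20.4% and 11.3% (-0.85, 0.232). NK-cell-like nuclei made up 1.67, 0.812 and 0.795% of controls 1, 2 and 3 and 6.46, 2.03 and 3.85% of knockouts 1, 2 and 3 (1.91, adjusted p = 0.0578, and 0.04 with classes by marker score; adjusted p from 0.034 to 0.925 over the alternatives). This class changed in what it held, with NK markers at 5010 CPM in the controls and 1458 in the knockouts, and no cluster took the name at Leiden resolution 2. Lymphatic endothelial-like nuclei were 0.198% and 0.570% (1.52, 0.0832). Adipocyte-like nuclei (25.4% and 21.6%, adjusted p = 0.768) and nuclei like adipose stem and progenitor cells (ASPC-like; 22.4% and 19.9%, adjusted p = 0.768) did not pass either. The adipocyte-like share leaves out an unnamed cluster closest to adipocytes, which held 30.5% of flox control 3. Among the nuclei of the adipocyte, ASPC, endothelial, mural and macrophage classes alone, a denominator chosen after seeing the data, 4 classes passed: endothelial (-0.71), mural (-0.86) and macrophage (-0.37) fell as parts of these nuclei and ASPC rose (0.32).

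The calls for B-cell-like and T-cell-like shares remained without knockout 2, where their adjusted p was 0.0386. They were lost without flox control 1, 2 or 3, at 0.0883, 0.185 and 0.0557 for B-cell-like and 0.0883, 0.185 and 0.088 for T-cell-like shares. They were also lost without knockout 1 (0.136 for both) and without knockout 3 (0.0927 and 0.136), with TMM factors (0.0552 for both) and with nuclei of at least 1000 genes (0.135 and 0.0731).

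**Figure D2:**
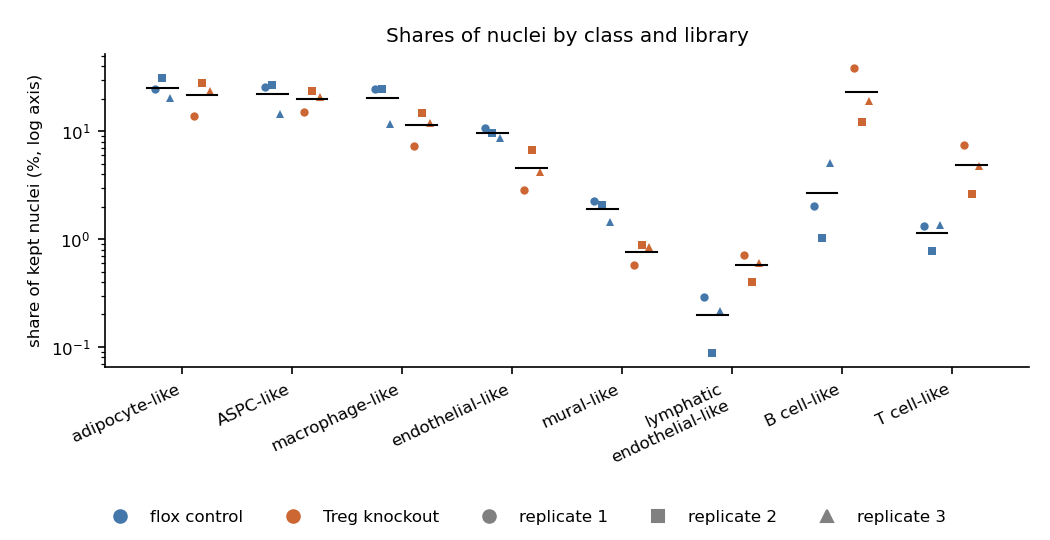
Share of kept nuclei (%, log axis) in 8 classes, with 1 point per library (flox control blue, Treg knockout orange) and the group mean as a horizontal line. B-cell-like and T-cell-like shares are higher in all 3 knockout libraries than in all 3 controls.

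Single genes known from lymphoid tissue were looked up after the shares had been seen, and none of them passed the edgeR test over the whole tissue. Over all kept nuclei, Ccl21a and Ccl19, chemokines of lymphoid stroma that attract T cells and dendritic cells, averaged 1.42 and 0.467 CPM in the controls and 15.9 and 8.94 CPM in the knockouts. Cxcl13, which attracts B cells into follicles, averaged 3.03 and 29.4 CPM, and Cr2, a complement receptor of B cells and follicular dendritic cells, 13.4 and 110 CPM. The summed level of Glycam1, Madcam1, Chst4 and Fut7, which serve lymphocyte entry through lymph node venules, was 0.661 ± 0.101 CPM in the controls and 3.04 ± 0.745 in the knockouts (SD, n = 3; 403 UMIs in all). All 3 knockout libraries lay above all 3 controls for each of these 5 measures.

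**Figure D3:**
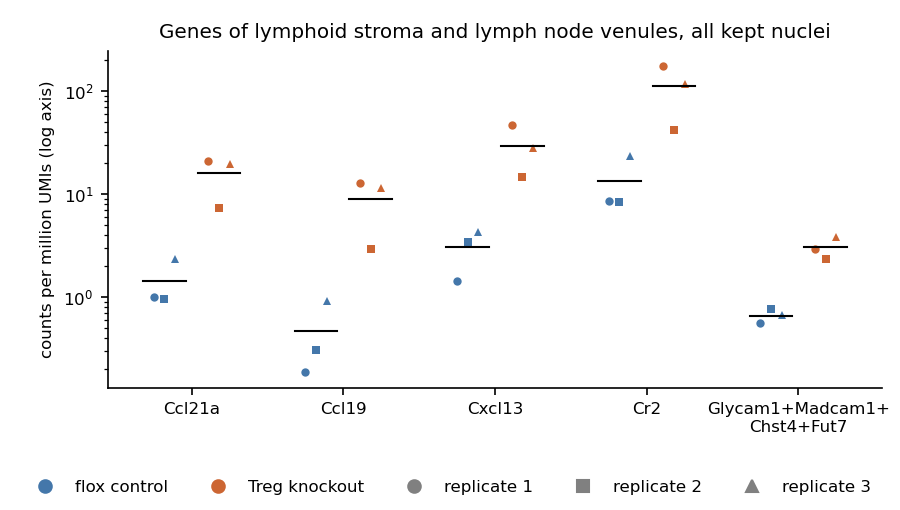
Level of 4 lymphoid genes and the summed level of 4 lymph node venule genes in each library, over all kept nuclei (CPM, log axis), with the group mean as a horizontal line. In each of the 5 measures the 3 knockout libraries lie above the 3 controls.

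Across the whole tissue, which mixes the cell types, 7 genes fell and 1 rose among 19310 tested. This balance depended on the processing. It was 1743 up and 1537 down with DESeq2, and 696 and 442 with a replicate block. With the adipose classes alone, chosen after seeing the data, it was 117 and 119. The largest fall was that of Lsmem1 (log2 fold change -1.80, SE 0.165, adjusted p = 0.0439), from 73.3 ± 14.9 to 20.99 ± 2.37 CPM (SD, n = 3). Ctnna3, which encodes a catenin of cell junctions (ENSMUSG00000060843; mm10 chromosome 10, 63430098 to 65003667), fell by 1.32 on the log2 scale, from 218.2 ± 7.64 to 87.3 ± 6.94 CPM (adjusted p = 0.023). The others were the sodium channel gene Scn8a (-1.29), the matrix gene Hmcn2 (-1.03), the collagen receptor gene Itga1 (-0.96), the endocytosis gene Epn2 (-0.93) and the fatty acid hydroxylase gene Cyp4v3 (-0.66). The gene that rose, 2010016I18Rik, is named although the naming rule passes it over, a choice made after its values were seen. Of the genes named for the study's question, none passed here: Nt5e was at 1.45 (adjusted p = 0.0658), Itgae at 1.05 (0.134), Foxp3 at 0.71, the interleukin 33 receptor gene Il1rl1 at -0.48, and Il10 at -0.44. The macrophage lipid receptor gene Trem2 was at -1.69 (adjusted p = 0.0689), the adipokine gene Lep at -0.44 (0.0744), the cytokine gene Tnf at 0.69 (0.0749), and the adenosine receptor gene Adora1 at -0.48 (0.0626). Adipoq was at -0.10, the uncoupling protein gene Ucp1 at -0.22, Il1b at -0.33, Ccl2 at -0.53, Lyve1 at 0.27 and Adora2a at 0.13, and Areg was too low to be tested.

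In the fixed gene lists, tested across the whole tissue, the lipid-associated macrophage list fell (20 of 21 members lower, median log2 fold change -0.74, adjusted p = 3.39e-06). MHC class II presentation rose (13 of 13 higher, adjusted p = 1.01e-04), as did the effector T cell list (15 of 16 higher, 0.00176) and the interferon response (20 of 23 higher, 8.72e-04). Angiogenesis fell (14 of 18 lower, 0.0022), as did fatty acid oxidation (17 of 18 lower, 0.00465). For these 6 lists the adjusted p was 0.695 with an estimated correlation. No single member passed over all genes, while 15, 11, 5, 9, 6 and 4 members in this order passed adjusted over the list alone. The Treg signature also rose (15 of 22 higher, adjusted p = 0.0409), with 0 members over all genes and 10 adjusted over the list alone (adjusted p = 0.711 with an estimated correlation). In the same libraries B-cell-like and T-cell-like shares were higher, and macrophage-like (20.4% and 11.3%), endothelial-like (9.68% and 4.55%) and mural-like shares (1.91% and 0.767%) were lower without passing. In whole tissue, 5456 genes had an unadjusted p under 0.05, and 34.0% had groups that did not overlap, against 10% by chance. edgeR called 0 genes without flox control 1, 2 or 3 and without knockout 1 or 3, where 4128, 4173, 4695, 4051 and 3711 genes had an unadjusted p under 0.05, and 1910 up and 1530 down without knockout 2.

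In adipocyte-like nuclei 177 genes rose and 223 fell among 15726 tested. With library totals alone as the scaling, the counts were 303 up and 138 down, and with nuclei of 3000 to 8000 UMIs 73 up and 218 down. The adipokine genes Cfd and Retn were among the 10 largest rises. Cfd, which encodes the adipokine adipsin (ENSMUSG00000061780; mm10 chromosome 10, 79890853 to 79892655), rose from 101 ± 9.10 to 510 ± 242 CPM (SD, n = 3; log2 fold change 2.34, SE 0.326, adjusted p = 0.0278). Retn, which encodes resistin (ENSMUSG00000012705; chromosome 8, 3655770 to 3660110), rose from 93.3 ± 8.25 to 180 ± 18.9 CPM (0.95, SE 0.102, adjusted p = 0.0138). Cyp2e1, a cytochrome P450 (1.86), the glucose transporter genes Slc2a3 (1.67) and Slc2a4 (0.61), Ces1f, a carboxylesterase (1.17), Prodh, which starts proline breakdown (0.94), and Pck1, the enzyme of glyceroneogenesis (0.86), rose too, as did Podn (1.46), Eva1c (1.36), Cadps2 (1.34) and the splicing factor gene Srsf7 (0.92).

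Of the genes that fell in adipocyte-like nuclei, Slit2, a secreted guidance protein (ENSMUSG00000031558; mm10 chromosome 5, 47983138 to 48307733), fell from 90.1 ± 11.9 to 23.9 ± 5.25 CPM (log2 fold change -1.92, SE 0.165, adjusted p = 0.0127). Col4a5, a basement membrane collagen (-2.22), Fstl1, a secreted glycoprotein (-1.29), Thbs1, a thrombospondin (-1.04), the lymphangiogenic factor gene Vegfc (-1.05) and its co-receptor gene Nrp2 (-1.08) fell as well. So did the ion channel genes Kcnc2 (-1.89) and Ryr2 (-1.35), and Lsmem1 (-1.49), Plekhh2 (-1.54), Lhfp (-1.54), Reps2 (-1.42) and Mark1 (-1.41). Adk, the kinase that removes adenosine, fell by 0.37 on the log2 scale, while Vegfb rose (0.51). Cxcl13 (3.19) and the thermogenic gene Cox8b (1.80) passed at mean levels of 0.85 and 1.72 CPM in the knockouts. Adipoq (0.30, adjusted p = 0.138), Lep (-0.07) and Adora1 (-0.12) did not pass, and Ucp1 was too low to be tested.

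Among the lists in adipocyte-like nuclei, adipokines rose (10 of 11 members higher, median 0.41, adjusted p = 9.22e-04). Of them 2 passed over all genes, Retn and Cfd, and 7 adjusted over the list alone. Nuclear-encoded oxidative phosphorylation rose (25 of 25 higher, median 0.20, adjusted p = 7.01e-04; 0 over all genes, 4 adjusted over the list alone), and was at 0.111 once each library's trend over gene length was removed. Both had an adjusted p = 0.695 with an estimated correlation. Proliferation fell (14 of 17 lower, adjusted p = 0.0206, and 0.695 with an estimated correlation; 0 members by either adjustment). The lipid-associated macrophage list also fell (13 of 18 lower, adjusted p = 0.019, and 0.703 with an estimated correlation), although its member Apoe, a lipid carrier, rose (0.92); adjusted over the list alone 1 rose and 4 fell. Its macrophage genes Gpnmb (-1.67), Mmp12 (-1.58) and Trem2 (-1.54) did not pass over all genes and stood at 5.27, 7.28 and 2.19 CPM in the controls, and free RNA of macrophages was not tested in this class. Macrophage markers here summed to 177 CPM in the controls and 195 in the knockouts. Across genes, which are not independent replicates, the fold change correlated with gene span (Spearman -0.366), and the genes that rose had a median span of 8 kb against 130.5 kb for those that fell. The makeup of the class differed, over the pooled nuclei of each group. The cluster led by Pck1, Nrg4, Nnat and Cfd made up 17.1% of it in the controls and 48.0% in the knockouts. This cluster had a median of 5103 UMIs per nucleus. The clusters led by Mageb18 and by Peg10, with medians of 13464 and 13166 UMIs, went from 33.1 and 20.1% to 16.5 and 8.1%.

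With the length trend removed, 20 genes rose and 18 fell in adipocyte-like nuclei. edgeR called 0 genes without flox control 1 or without knockout 2, with 2767 and 2816 genes at an unadjusted p under 0.05. The counts were 4 up and 14 down without flox control 2, 75 up and 137 down without flox control 3, 240 up and 260 down without knockout 1, and 6 up and 15 down without knockout 3. The groups did not overlap for 28.7% of genes, against 10% by chance.

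**Figure D4:**
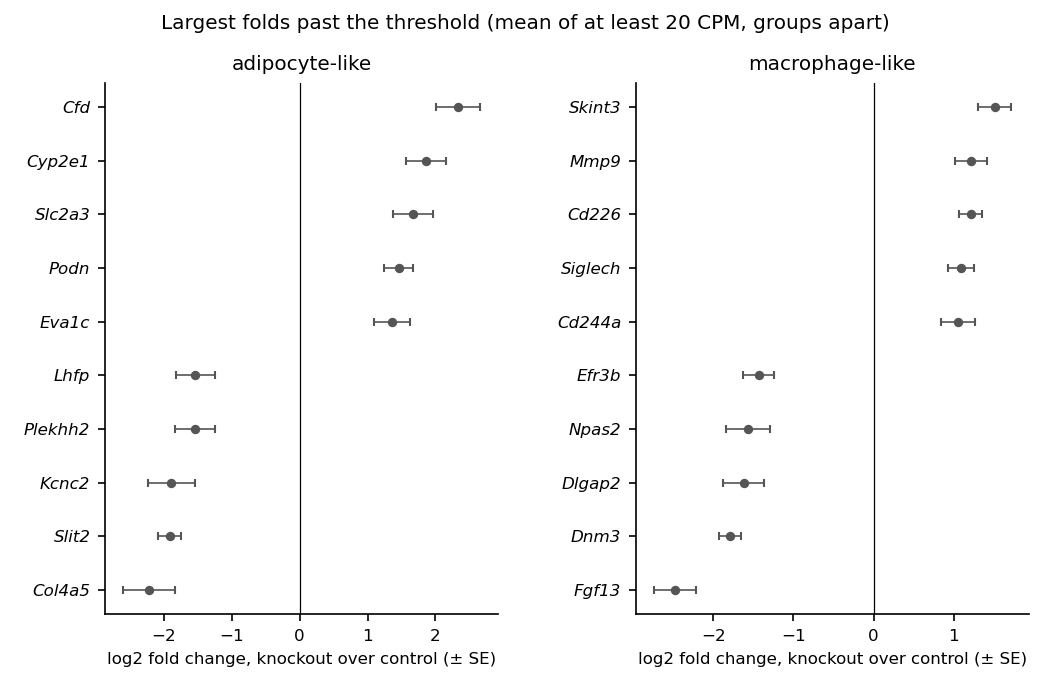
Log2 fold changes (knockout over control, ± SE) in adipocyte-like and macrophage-like nuclei of the 5 genes each way with the largest folds among genes past the threshold that had a mean of at least 20 CPM and groups that did not overlap, with predicted genes passed over. In adipocyte-like nuclei they run from 2.34 (Cfd) to -2.22 (Col4a5), and in macrophage-like nuclei from 1.51 (Skint3) to -2.48 (Fgf13).

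In ASPC-like nuclei 24 genes rose and 25 fell among 13761 tested. Hmcn2, which encodes the matrix protein hemicentin 2 (ENSMUSG00000055632; mm10 chromosome 2, 31314415 to 31460738), fell by 1.10 on the log2 scale (SE 0.085, adjusted p = 9.96e-04). Fry (-0.96), the acyl-CoA thioesterase gene Acot7 (-0.87), Eepd1 (-0.85), Lhfpl2 (-0.82), Fhl2 (-0.80), Myo1d (-0.77), Zbtb46 (-0.75) and Pdzrn3 (-0.73) fell with it. Genes that rose included the ribosomal protein genes Rpl8 (0.82), Rpl13 (0.73), Rps7 (0.70) and Rplp0 (0.68). Others were Fyb2 (0.93), Mrgprg (0.80), the adhesion receptor gene Adgrg6 (0.77), the aldehyde oxidase gene Aox3 (0.71) and the kinase gene Syk (0.66). The rise of ribosomal protein genes was not particular to this class. They were higher for 80 of 80 tested in ASPC-like and 81 of 82 in adipocyte-like nuclei. In macrophage-like, endothelial-like and T-cell-like nuclei it was 78 of 80, 78 of 80 and 73 of 77. Those that rose past the threshold numbered 13, 27, 3, 0 and 1 in this order.

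Of the lists in ASPC-like nuclei, the interferon response rose (21 of 22 higher, median 0.24, adjusted p = 0.00106; 0 members by either adjustment). De novo lipogenesis (14 of 17 lower, 7.01e-04), lipolysis (11 of 13 lower, 0.00498), triglyceride synthesis (8 of 9 lower, 0.0143) and fatty acid oxidation (14 of 18 lower, 0.0282) fell. The lipid-associated (15 of 17 lower, 1.37e-04) and resident macrophage (11 of 12 lower, 7.01e-04) lists fell too. These 7 lists had an adjusted p of 0.695 with an estimated correlation. Extracellular matrix and fibrosis fell (23 of 27 lower, adjusted p = 0.0179, and adjusted p = 0.774 with an estimated correlation). None of these members passed over all genes, and adjusted over the list alone 1 fell in each of de novo lipogenesis, lipolysis and the lipid-associated list, 4 in the resident list and 0 in the others. Macrophage markers in ASPC-like nuclei summed to 145 CPM in the controls and 75.3 in the knockouts, and adipocyte markers to 362 and 261. RNA carried over from adipocytes was not tested here.

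Over the pooled nuclei of the ASPC-like class, the cluster led by Pde11a, Col3a1 and Bmper made up 36.9% in the controls and 30.4% in the knockouts. Hmcn2 is a leading gene of this cluster. That led by Sema3e and Rorb made up 54.2% and 60.5%. By library the groups overlapped for the Pde11a cluster, with 840 of 2387 nuclei in control 1 and 810 of 2229 in knockout 2. Counts in ASPC-like nuclei were 14 up and 9 down without flox control 1, 0 and 2 without flox control 2, 3 and 5 without flox control 3, 11 and 4 without knockout 1, and 0 and 1 without knockout 3. The groups did not overlap for 16.6% of genes, against 10% by chance, and fold change correlated with gene span across genes (Spearman -0.203).

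In macrophage-like nuclei 55 genes rose and 88 fell among 12379 tested. Cell division genes fell together: the proliferation list was lower in 20 of 20 members (median -0.76, adjusted p = 8.6e-14, and 0.695 with an estimated correlation), with 4 down over all genes and 16 adjusted over the list alone. Those 4 were Mki67 (-0.80), the kinesin gene Kif15 (-0.95), the kinetochore gene Knl1 (-0.82) and the formin gene Diaph3, which fell from 130 ± 4.86 to 73.1 ± 7.76 CPM (-0.83; SD, n = 3). Ccr2, the receptor by which monocytes enter tissue (ENSMUSG00000049103; mm10 chromosome 9, 124101950 to 124113557), rose from 160 ± 14.6 to 302 ± 65.7 CPM (0.91, SE 0.144, adjusted p = 0.0272). Fn1, fibronectin (ENSMUSG00000026193; chromosome 1, 71585520 to 71653200), rose from 290 ± 57.1 to 596 ± 73.0 CPM (1.03, SE 0.148, adjusted p = 0.0254). The matrix protease gene Mmp9 (1.21), the receptor genes Cd226 (1.21), Siglech (1.09) and Cd244a (1.05), and Skint3 (1.51), Ms4a8a (0.99), Arhgef18 (0.89) and Ntng2 (0.87) rose as well. Dnm3, a dynamin of membrane scission (ENSMUSG00000040265; chromosome 1, 161982453 to 162478034), fell from 75.4 ± 10.1 to 21.8 ± 2.07 CPM (-1.79, SE 0.138, adjusted p = 5.8e-04). Fgf13 (-2.48), Dlgap2 (-1.62), the clock factor gene Npas2 (-1.57), Efr3b (-1.43), the ubiquitin ligase gene Rnf128 (-1.24), C77080 (-1.21), Dach1 (-1.13), the chromatin remodeller gene Hells (-1.08) and Pparg, the lipid-sensing nuclear receptor (-0.60), fell too.

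The macrophage lists moved in both directions. The lipid-associated list, which holds genes of lipid uptake and lysosomes, fell (20 of 21 lower, median -0.51, adjusted p = 9.36e-07; 0 over all genes, 7 adjusted over the list alone), and its member Trem2 was at -0.96 (adjusted p = 0.191). The resident macrophage list rose (15 of 16 higher, median 0.47, adjusted p = 3.39e-06), with Cbr2 (0.81) past the threshold over all genes and 6 adjusted over the list alone, and Lyve1 at 0.81 (adjusted p = 0.264). The interferon response rose (20 of 21 higher, median 0.35, adjusted p = 1.58e-05), with Gbp7 (0.60) over all genes and 9 adjusted over the list alone. MHC class II presentation rose (11 of 12 higher, median 0.47, adjusted p = 1.14e-04; 0 over all genes, 3 adjusted over the list alone). Extracellular matrix and fibrosis fell (22 of 24 lower, adjusted p = 1.01e-04), although its members Fn1 and Tgfbi (0.63), both matrix proteins, rose, while the receptor gene Tgfbr1 fell (-0.65); adjusted over the list alone 2 rose and 3 fell. Senescence fell (10 of 11 lower, adjusted p = 0.03; 0 by either adjustment). All 6 had an adjusted p = 0.695 with an estimated correlation. Tnf (-0.36), Ccl2 (-0.75) and Il10 (0.10) did not pass.

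The makeup of the macrophage-like class, over the pooled nuclei of each group, differed with these lists. The cluster led by Atp6v0d2, Gpnmb and Trem2 made up 34.2% of it in the controls and 17.2% in the knockouts, and that led by Kif15, Diaph3 and Kif11 made up 5.0% and 2.1%. The cluster led by Cd163 and F13a1 made up 51.5% and 64.3%, and that led by Fcrls, Lyz1 and Retnla 9.2% and 16.5%. B-cell markers in macrophage-like nuclei summed to 289 CPM in the controls and 518 in the knockouts. The groups did not overlap for 19.8% of genes, against 10% by chance. Counts fell to 1 up and 1 down without flox control 1 or knockout 1, 0 and 5 without flox control 3, and 1 and 2 without knockout 3, and rose to 194 and 278 without knockout 2.

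**Figure D5:**
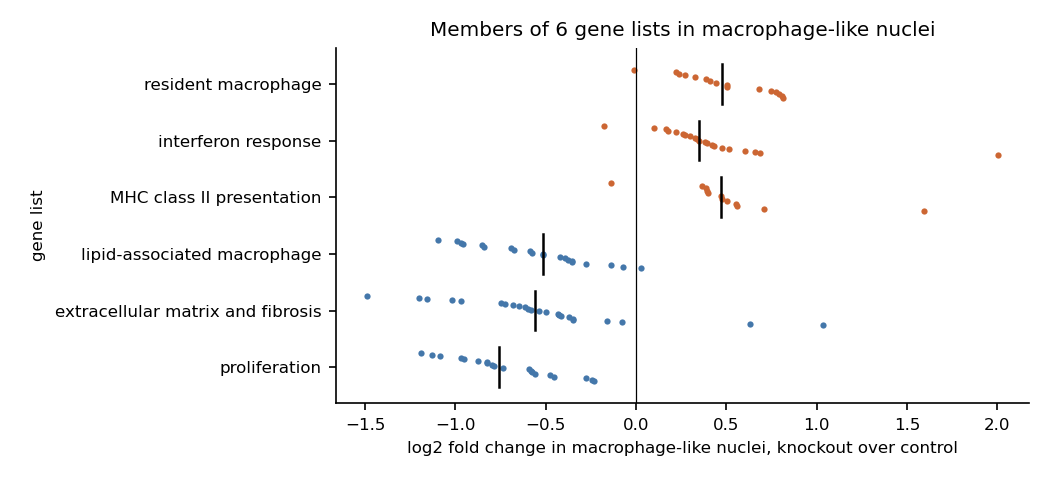
Log2 fold change (knockout over control) in macrophage-like nuclei of each measured member of 6 gene lists, with 1 point per gene and the list median as a black bar. All 20 members of the proliferation list lie below 0, and 15 of 16 members of the resident macrophage list lie above 0.

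In endothelial-like nuclei 8 genes rose and 3 fell among 10487 tested. Eln, the elastin gene (ENSMUSG00000029675; mm10 chromosome 5, 134702593 to 134747323), rose from 868 ± 42.5 to 1360 ± 69.9 CPM (SD, n = 3; log2 fold change 0.65, SE 0.103, adjusted p = 0.0246), with Clu, clusterin (0.96), Cp, ceruloplasmin (0.82), Cytl1 (0.82), Setbp1 (0.70) and the nuclear receptor gene Esrrg (1.81). Tspan18, a tetraspanin (ENSMUSG00000027217; chromosome 2, 93201760 to 93334505), fell from 189 ± 19.7 to 89.1 ± 14.5 CPM (-1.09, SE 0.144, adjusted p = 0.0114), with the amino acid transporter gene Slc7a10 (-1.76) and the ephrin receptor gene Ephb1 (-1.05). Nxph1 (6.85) had 3 UMIs in the controls and 180 in the knockouts, a ratio of CPM of 139 (95% counting interval 46.9 to 682). Of the 180, 178 lay in 7 nuclei of 1 cluster. The interval treats each UMI as independent and is therefore too narrow. The remaining gene that rose, Ccl21a, falls outside the naming rule and is named after its values were seen. Immediate early and heat shock genes rose as a list (14 of 16 higher, adjusted p = 0.00524), and de novo lipogenesis (11 of 15 lower, 0.00455) and triglyceride synthesis (9 of 9 lower, 0.00839) fell, all at adjusted p = 0.695 with an estimated correlation. The lipid-associated macrophage list fell (12 of 15 lower, adjusted p = 0.0155, and 0.711 with an estimated correlation). None of these members passed over all genes or adjusted over the list alone. Adipocyte markers in this class summed to 737 CPM in the controls and 529 in the knockouts, and carried-over RNA was not tested here. Slc7a10 is also a leading gene of an unnamed cluster closest to adipocytes.

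Over the pooled nuclei of the endothelial-like class, the cluster led by Cytl1 and Mgp made up 17.4% in the controls and 22.4% in the knockouts. That led by Car4 and Ccdc85a made up 74.6% and 66.4%. By library the groups overlapped for the Car4 cluster, with 648 of 880 nuclei in control 2 and 209 of 277 in knockout 1. Counts in endothelial-like nuclei were 42 up and 13 down without flox control 1, and 0 and 1 without flox control 2. edgeR called 0 genes without flox control 3 or knockout 2 (731 and 772 at an unadjusted p under 0.05) and 5 up and 2 down without knockout 3. With classes assigned by marker score it called 0 genes, with 730 at an unadjusted p under 0.05. The groups did not overlap for 13.6% of genes, against 10% by chance.

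In mural-like nuclei no gene passed in edgeR among 5652 tested, with 258 at an unadjusted p under 0.05, while DESeq2 called 1 gene up. The 5 genes with the smallest p had not passed: the serotonin receptor gene Htr7 (log2 fold change 1.62) and the dynein gene Dnah7b (-2.16), both at an adjusted p of 0.440, Etl4 (-1.67) and the planar polarity gene Prickle2 (-0.80), both at 0.556, and the glypican gene Gpc6 (-0.72, 0.834). As lists, lipolysis fell (9 of 10 lower, adjusted p = 0.0109; 0 members by either adjustment), as did the lipid-associated macrophage list (9 of 10 lower, 0.00465; 0 over all genes, 2 adjusted over the list alone), both at adjusted p = 0.695 with an estimated correlation. Adipocyte markers in this class summed to 747 ± 216 CPM in the controls and 595 ± 190 in the knockouts and macrophage markers to 620 ± 352 and 353 ± 57.3 (SD, n = 3), and carried-over RNA was not tested here. edgeR called 1 gene up without flox control 3 and 2 up without knockout 2. The groups did not overlap for 11.1% of genes, against 10% by chance. The class held 530 control and 218 knockout nuclei.

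In T-cell-like nuclei 84 genes rose and 155 fell among 5488 tested. The class held 318 control and 1408 knockout nuclei, of which 12 and 52 were Foxp3-positive. The folds are those of the whole class, whose share of kept nuclei rose by 2.10 on the log2 scale. Its summed UMIs ran from 103967 to 245757 in the controls and from 365804 to 1250915 in the knockouts. A gene confined to nuclei that did not become more numerous would fall by about as much in CPM. The fall of Il1rl1 given below (-2.39, SE 0.347) is of that size, so it does not show less Il1rl1 per Treg cell. Whether the folds lie in Treg cells or follow the makeup of the class was not tested. Lymph node tissue, which stays open for the shares, was not tested as a source of these changes either. Il1rl1, which encodes ST2, the interleukin 33 receptor carried by Treg cells of adipose tissue (ENSMUSG00000026069; mm10 chromosome 1, 40429570 to 40465415), fell from 251 ± 118 to 50.2 ± 15.8 CPM (SD, n = 3; log2 fold change -2.39, SE 0.347, adjusted p = 0.00134). Transcription factor genes that fell included Gata3 (-1.10), Rora (-1.23), Maf (-0.90), Klf6 (-1.21), Nr3c1 (-0.59) and Pparg (-1.94), which adipocytes and macrophages express as well as adipose Treg cells. Itgb8, an integrin chain that activates TGF-beta (ENSMUSG00000025321; chromosome 12, 119158022 to 119238802), rose from 5.57 ± 5.37 to 63.6 ± 23.6 CPM (3.96, SE 0.690, adjusted p = 0.00161). The activation genes Tnfrsf9, which encodes 4-1BB (2.79), and Cd69 (1.82), the folate receptor gene Izumo1r (2.41), and Gpm6b (2.82), Ms4a4c (2.11), Lypd6b (1.999), Ptprk (1.87), Ttn (1.69), Dpp4 (0.72), Tbc1d4 (1.01) and the exhaustion-linked factor gene Tox (0.63) rose. Genes that fell also included Pde7b (-2.88), Pram1 (-2.41), Tdrd9 (-2.40), Pcyt1a (-2.29), Lama4 (-2.17), Pard3 (-2.15), Rap1gap2 (-2.14), Stxbp6 (-2.13) and the leukotriene receptor gene Ltb4r1 (-2.13).

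The interferon response rose as a list in T-cell-like nuclei (9 of 9 higher, median 0.55, adjusted p = 7.01e-04), with Parp14 (0.98) among the members past the threshold over all genes and 3 adjusted over the list alone. MHC class II presentation rose (5 of 5 higher, adjusted p = 0.00839), with Cd74 (1.13) over all genes and 3 adjusted over the list alone. The lipid-associated macrophage list fell (9 of 12 lower, adjusted p = 0.019), with the lipid receptor gene Cd36 (-1.37), Ctsl (-1.67) and Lgals3 (-1.84) over all genes, and 5 down and 1 up adjusted over the list alone. Members that are also adipocyte genes were lower with them, such as Fabp4 (1720 and 1200 CPM) and Lpl (324 and 152), which did not pass. Adipocyte markers in this class summed to 1130 ± 244 CPM in the controls and 1036 ± 22.0 in the knockouts and macrophage markers to 219 ± 119 and 170 ± 22.6 (SD, n = 3), and RNA carried over from these cells was not tested here. These 3 lists had an adjusted p of 0.695 with an estimated correlation. The Treg signature did not pass (10 of 15 higher, 1 up and 3 down by either adjustment), and its test pointed down while its median (0.17) and mean (0.03) lay above 0. B-cell markers in this class summed to 50.5 CPM in the controls and 233 in the knockouts, and the B-cell adaptor gene Bank1 was among the genes that rose (2.35). Over pooled nuclei, the cluster led by Cd5, Ctla4 and Lef1 made up 75.8% of the class in the controls and 89.2% in the knockouts. That led by Cd163l1, Il23r and Olfr60 made up 24.2% and 10.8%. Counts were 21 up and 55 down without flox control 1, 47 and 83 without knockout 1, and 37 and 87 without knockout 3, and the groups did not overlap for 20.2% of genes, against 10% by chance.

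The other classes with enough nuclei were B-cell-like (15 genes up and 5 down among 9303), NK-cell-like (151 up and 258 down among 5381) and dendritic-like, in which edgeR called 0 of 4219 genes with 373 at an unadjusted p under 0.05. In the NK-cell-like class T-cell markers summed to 7090 CPM in the controls and 11299 in the knockouts while NK markers were lower, so its genes are not listed. Over all classes, 35 of 143 list tests passed, 13 up and 22 down. Other splits of the 6 libraries, looked at after the result, gave 11 to 33 list calls. The lipid-associated macrophage list fell in 7 of the 7 classes in which it was tested, the whole tissue included, and RNA carried over from macrophages was tested for it in ASPC-like nuclei only. With an estimated correlation 0 passed, 7 at an unadjusted p under 0.05, and fry, which asks whether the genes of a list move one way, called 2: fatty acid oxidation in ASPC-like and de novo lipogenesis in mural-like nuclei (adjusted p = 0.047 for both). The lists that passed in no class had their lowest adjusted p as follows: adenosine axis 0.108 and inflammatory cytokines 0.324 in macrophage-like nuclei, futile creatine and calcium cycling 0.174 in endothelial-like nuclei, adipogenic transcription factors 0.245 in T-cell-like nuclei, insulin signalling 0.31 in ASPC-like nuclei and hypoxia 0.618 in endothelial-like nuclei. The thermogenic list was at 0.199 in endothelial-like nuclei, where its mean was above 0 (0.32) and its median below (-0.02).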

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

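Among the tests below, the comparison with B-cell RNA, the form of the MHC class II ratio, every count over other splits of the libraries, and the alternatives with a length correction, a shared window of UMIs or adipose classes alone were chosen only after the result was seen.

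B-cell-like and T-cell-like nuclei took a larger share of the knockout libraries, with log2 fold changes of 3.11 and 2.10. A gain of small, shallow nuclei in the shallower knockout libraries is argued against: among nuclei of at least 1000 genes the B-cell-like share was still at 2.64, although the call ended (adjusted p = 0.135, within 0.0159 to 0.185 over all its alternatives) and the SE grew from 0.789 to 1.128. Lymph node tissue in the knockout samples stays open, since the summed level of Glycam1, Madcam1, Chst4 and Fut7, which no earlier step had looked at, was 4.6 times as high in the knockouts, at 0.559, 0.761 and 0.662 CPM in controls 1, 2 and 3 and 2.93, 2.35 and 3.83 in knockouts 1, 2 and 3. All 3 knockouts lay above all 3 controls, which met the prediction written beforehand for such tissue. Chst4 alone had 7 UMIs, with a ratio of 0.902. The unnamed cluster led by Pcdh15, Cxcl13, Robo2 and Ccl19 held 0.029% of control and 0.846% of knockout nuclei on average. A node included at dissection and lymphoid tissue that forms within the fat after the deletion may both carry these genes, and the second, a biological difference, was not tested.

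In adipocyte-like nuclei, 400 genes changed, and those that rose were shorter than those that fell. A gene length bias as the whole cause of the folds is argued against, since the median ratio of length-corrected to uncorrected log2 fold changes was 0.828 (quartiles 0.705 to 0.928). The sign was the same for 400 of 400 genes. These genes were chosen by their folds in the same counts, which makes a turned sign unlikely and favours a high ratio. The calls did end for most of them: 38 genes passed after the correction, 37 of them among the 400, and the folds became smaller while the median SE went from 0.116 to 0.117. Fewer UMIs per knockout nucleus are also argued against as the whole cause, with a median ratio of 0.902 (0.709 to 1.151) among nuclei of 3000 to 8000 UMIs, whose medians were brought closer but not equal (5832, 5616.5 and 5621 in controls 1, 2 and 3, and 5675.5, 4883 and 5041 in knockouts 1, 2 and 3), and where 137 of 372 genes still passed and the median SE went from 0.108 to 0.157. What stays open is the part of the folds that the length trend took and the shift between clusters of unlike depth within the class. An effect of the genotype on adipocytes, which was not tested, and the part of flox control 3 stay open too. The correlation of that library with gene span (0.453) lay apart from 0.204 and 0.056 in the other controls. Of its nuclei, 30.5% sit in an unnamed cluster closest to adipocytes. Knockouts 1, 2 and 3 were at -0.289, -0.271 and -0.206, so the trend also separated the groups.

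In macrophage-like nuclei the MHC class II list was higher and the proliferation and lipid-associated lists were lower. For MHC class II, the summed list rose 9.56 times as much as in ASPC-like nuclei, with the first rise lowered and the second raised by 1 SE. This ratio assumes the same free RNA in both classes. B-cell markers went from 289 to 518 CPM in macrophage-like and from 23.9 to 81.9 CPM in ASPC-like nuclei, so it cannot decide on free RNA. RNA of B cells as the whole cause is argued against, since their markers account for 12.3% of the rise of the list (164 of 1337 CPM, SE 750), or 27.9% of the rise less 1 SE. The groups overlapped for the summed list, with 4741 CPM in control 1 and 4593 in knockout 3. RNA of other cells was not tested. Gene length is argued against for the other 2 lists, whose median log2 fold change was -0.587 before and -0.584 after the length correction. The lower lipid-associated list in ASPC-like nuclei cannot be told apart from free RNA of macrophages, since its macrophage-restricted members stood at a median of 3.41% of their macrophage level there, while Gpnmb stood at 16.02% and Spp1 at 7.1%. A genotype effect on macrophages and a shift between macrophage clusters both stay open, and neither was tested.

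The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. In whole tissue the real split called 8 genes and the highest other split 0. The real and the highest other count were 400 and 0 in adipocyte-like, 49 and 4 in ASPC-like, 143 and 0 in macrophage-like, 11 and 6 in endothelial-like, and 239 and 0 in T-cell-like nuclei. For the class shares they were 2 and 0, and for the gene lists 35 and 33. In each of these, 1 of the 10 splits, the real one, gave as many. Every other split also gave list calls, from 11 to 33, so camera with its preset correlation called lists under each grouping. In mural-like nuclei 10 of the 10 splits gave as many as the real split, which called 0, and the split that put flox controls 1 and 2 with knockout 2 called 9.

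Signals outside the named classes came from clusters that took no name. The cluster led by Pcdh15, Cxcl13, Robo2 and Ccl19 held 0.846% of knockout nuclei against 0.029% of control nuclei on average, with 0, 0 and 8 nuclei in controls 1, 2 and 3 and 142, 27 and 74 in knockouts 1, 2 and 3. The cluster led by Asic2, Timd4, Cd209b and Marco held 0.394% against 0.018%, with 0, 0 and 5 nuclei in controls 1, 2 and 3 and 62, 9 and 42 in knockouts 1, 2 and 3.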

How the results depend on the processing

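The results on the adipose classes alone, the length correction and the shared windows of UMIs below were chosen after the data were seen. Of the 134 named genes past the threshold (counted per class), 2179 refits gave 1355 calls in the same direction and 824 below the threshold, and 0 reversed. For the largest folds the naming rule asks for groups that do not overlap, so refits of the same counts could hardly turn a sign. Of 36 named genes not past the threshold, 564 refits gave 521 of the same kind, 25 past the threshold and 18 of the opposite sign. Of the 35 list calls, 17 passed under every alternative recomputed with camera and its preset correlation, among them proliferation, lipid-associated and resident macrophage, interferon response, MHC class II and extracellular matrix in macrophage-like nuclei and adipokines in adipocyte-like nuclei. The counts of changed genes stayed close with RLE factors and at Leiden resolution 2, except that T-cell-like nuclei gave 91 up and 222 down at resolution 2. The exact permutation test of the shares cannot pass with 3 against 3. Its p was 0.1, the smallest it can give, for both the B-cell-like and the T-cell-like share.

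The counts of changed genes, whole tissue first, then changed genes, adipocyte-like, changed genes, ASPC-like, changed genes, macrophage-like, changed genes, endothelial-like, changed genes, T cell-like, and changed genes, mural-like, follow in this order. With DESeq2 they were 3280, 1262, 175, 391, 26, 125 and 1, and without a filter on low counts 269, 732, 399, 1136, 251, 362 and 36. With a replicate block they were 1138 in whole tissue, 111 up and 250 down in adipocyte-like, 11 in ASPC-like, 23 in macrophage-like, 22 in endothelial-like and 128 in T-cell-like nuclei, and 4 class shares passed. In whole tissue, deviations from the group means correlated at -0.049, 0.409 and 0.09 between libraries of the same number. Flox control 3 correlated best with knockout 1 (0.449), so pairing by number was not evident. With 3 libraries per group these correlations are tied to one another, so they cannot exclude such pairing. Without doublet removal the counts were 30 in adipocyte-like, 22 in macrophage-like, 2 in endothelial-like and 156 in T-cell-like nuclei. With classes by marker score they were 80 in adipocyte-like, 22 in ASPC-like, 3 in macrophage-like, 82 in T-cell-like and 1 in mural-like nuclei, and 0 in endothelial-like nuclei (730 at an unadjusted p under 0.05). With nuclei of at least 1000 genes they were 2 in endothelial-like and 148 in T-cell-like nuclei. With the length trend removed they were 1 in whole tissue, 38 in adipocyte-like and 27 in ASPC-like nuclei. A shared window of UMIs gave 14 in macrophage-like nuclei, library totals 1 in whole tissue, and the adipose classes alone 236 in whole tissue. Over the changed genes of macrophage-like nuclei, the median ratio of folds in that window to the main folds was 0.943. The sign was the same for 138 of 138, genes chosen by their folds in counts that include these nuclei. The median SE went from 0.146 to 0.19. Leaving out 1 library gave 0 to 3440 in whole tissue, 0 to 500 in adipocyte-like, 1 to 42 in ASPC-like, 2 to 472 in macrophage-like, 0 to 55 in endothelial-like, 76 to 272 in T-cell-like and 0 to 2 in mural-like nuclei. The cause of each of these shifts was not tested.

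Of the class shares, 0 passed with TMM factors, at log2 fold changes of 3.79 for B-cell-like and 2.78 for T-cell-like nuclei, and 0 with nuclei of at least 1000 genes (2.64 and 2.25). With the adipose classes alone 4 passed, and 0 to 3 passed when 1 library was left out. The fold then ran from 2.54 to 3.93 for B-cell-like and from 1.68 to 2.40 for T-cell-like nuclei. For the adipocyte-like share, log2 fold change -0.23, the sign turned with TMM factors (0.20) and the adipose classes alone (0.19), and leaving out 1 library gave -0.45 to 0.009, the last without knockout 1. It was -0.66 without doublet removal, where 49.3% of flox control 3 was adipocyte-like against 20.2% with it. For the ASPC-like share, log2 fold change -0.17, it turned with TMM factors (0.31), the adipose classes alone (0.32) and at least 1000 genes (0.012). Of the gene lists past threshold, 2 passed with fry and 0 with an estimated correlation, where 7 had an unadjusted p under 0.05. The Foxp3-positive share of T-cell-like nuclei differed by -0.557 percentage points, and by -1.014 with nuclei thinned to 1000 UMIs (3.53% and 2.51%, exact permutation p = 0.2). With at least 2 of 6 Treg genes as the definition the difference was -4.04, and per 10000 kept nuclei it was 13.7, since the T-cell-like class was larger. The causes of the other changes were not tested.

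Signs turned for named genes that had not passed. With the adipose classes alone, Ikzf2 in whole tissue was at -0.024, Il2ra in whole tissue at -0.026, Il1b in whole tissue at 0.51, Adora2a in whole tissue at -0.69, Itgae in whole tissue at -0.33, Adipoq in whole tissue at 0.23 and Tnf in whole tissue at -0.48. Lep in adipocyte-like nuclei was at 0.002 with library totals and between -0.17 and 0.00 with 1 library left out, and Adora1 in adipocyte-like nuclei was at 0.11 within the shared window of UMIs. Etl4 in mural-like nuclei was at 0.30 without doublet removal, and with classes by marker score it was at 0.55, Prickle2 in mural-like nuclei at 0.25 and Gpc6 in mural-like nuclei at 0.97. With 1 library left out, Ucp1 in whole tissue ran from -1.11 to 0.30, Adora2a in whole tissue from -0.18 to 0.52 and Il10 in macrophage-like nuclei from -0.072 to 0.24. The cause was not tested.

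List calls were lost most often when flox control 1 or knockout 3 was left out. The highest adjusted p in ASPC-like nuclei was 0.371 for extracellular matrix, 0.169 for lipolysis, 0.158 for interferon response, 0.0844 for fatty acid oxidation and 0.0528 for triglyceride synthesis. In adipocyte-like nuclei it was 0.112 for the lipid-associated list, 0.111 for oxidative phosphorylation (length trend removed) and 0.078 for proliferation. In endothelial-like nuclei it was 0.280 for the lipid-associated list, 0.182 for immediate early genes, 0.152 for triglyceride synthesis and 0.0799 for de novo lipogenesis. For the lipid-associated list it was 0.411 in mural-like and 0.398 in T-cell-like nuclei, for mural-like lipolysis 0.247, for macrophage-like senescence 0.138, and in whole tissue 0.129 for the Treg signature and 0.0533 for fatty acid oxidation. The cause was not tested.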

Other observations

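B-cell-like nuclei showed 15 genes up and 5 down among 9303 tested. Cd83, a marker of activated B cells and antigen-presenting cells, rose from 131 ± 19.0 to 273 ± 69.0 CPM (SD, n = 3; log2 fold change 1.05, adjusted p = 0.0187). Cd52, a surface glycoprotein of lymphocytes, rose from 288 ± 62.5 to 552 ± 25.2 CPM (1.01, adjusted p = 0.00418), and H2-DMa, which loads peptides onto MHC class II, rose from 76.4 ± 15.8 to 141 ± 12.5 CPM (1.03, adjusted p = 0.0183). Dexi (1.11), Il4i1 (1.02), Tmem126a (1.002) and Lgals8 (0.76) rose too, while the phospholipase gene Plcb1 (-1.59), Cecr2 (-0.88) and Lars2 (-0.79) fell. A B-cell-like cluster led by the interferon-inducible genes Ifi214 and Ifi213 held 2, 2 and 3 nuclei in flox controls 1, 2 and 3 and 45, 11 and 418 in knockouts 1, 2 and 3.

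Other unnamed or minor groups of nuclei were spread unevenly over the libraries. The cluster led by Slco1b2, Cps1, Alb and Mug1, genes known from liver cells, held 0, 12 and 112 nuclei in flox controls 1, 2 and 3 and 0, 15 and 10 in knockouts 1, 2 and 3. An unnamed cluster closest to adipocytes, with a median of 1208 UMIs per nucleus, held 2839 nuclei of flox control 3, or 30.5% of that library, against 43 and 33 in controls 1 and 2 and 13, 22 and 218 in knockouts 1, 2 and 3. A cluster with both T-cell and B-cell markers held 348 nuclei of knockout 3, against 12 and 11 in knockouts 1 and 2 and 5, 0 and 43 in controls 1, 2 and 3. Skeletal muscle-like nuclei numbered 109 in flox control 3 and 71 in knockout 2, against 0, 0, 0 and 1 in the others. Epithelial-like nuclei made up 3.14, 0.143 and 0.633% of controls 1, 2 and 3 and 1.60, 4.33 and 0.118% of knockouts 1, 2 and 3.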
